A study of Arabidopsis thaliana with 10 samples.

How the data were processed

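Gene-level read counts were analysed for 10 libraries of whole Arabidopsis thaliana seedlings, 5 groups of 2: Col-0, Col-0 on 10 µM Dex, DIF-OX2, DIF-OX2 on 10 µM Dex, and dal-2. Per the labels, seedlings were harvested with 4 open true leaves, at 12 days for Col-0 and DIF-OX2 and at 20 and 21 days for dal-2, and groups without Dex received 0.1% ethanol. The deposited count table was made by the authors, who trimmed reads with Trimmomatic, aligned them to the TAIR10 genome with TopHat2 and counted reads per gene with HTSeq; no versions are stated. Neither the strand setting nor the handling of reads with several alignments is stated, so counts of near-identical genes cannot be split with certainty. The count values were checked to be whole numbers of at least 0, and 0 columns of the table belonged to no sample. Names and product descriptions came from the TAIR10.1 annotation, which had an entry for 32835 of the 33602 genes.

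The analysis ran in R 4.3.3. Genes were kept by edgeR's filterByExpr (20681 tested, 12921 removed), libraries were scaled by TMM, and a quasi-likelihood negative binomial model with 1 coefficient per group was fitted to all 10 libraries in edgeR 4.0.16 (residual degrees of freedom 5, prior degrees of freedom 3.27, common biological coefficient of variation 0.188). P-values were adjusted over all tested genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p of 0.05. The 6 comparisons were DIF-OX2 against Col-0 with both on Dex, dal-2 against Col-0, Dex in DIF-OX2, Dex in Col-0, the difference between both Dex effects, and DIF-OX2 against Col-0 without Dex. The first of these and the dal-2 comparison are the main ones. Their fold changes were also compared by correlation and by the number of shared calls against the number that independent lists would give.

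The 24 gene lists were fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, and again with an estimated correlation, and were tested on their own by fry. Counts of members are given at an adjusted p over all genes and over the list alone. Where a group had no count for a gene, the fold is a bound with 3 counts over that group, and with 1 to 3 counts it is a ratio with a 95% counting interval.

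Named genes followed a rule fixed in advance. They are DAL, the 6 largest rises and 6 largest falls of each main comparison among called genes with a mean count of at least 50 and non-overlapping groups, up to 2 rises and 2 falls of each list with its first member, and the 4 largest rises and falls of the other comparisons. The 4 genes per direction with the largest smaller change of both main comparisons complete the set. The locus of DIF is not given in the sources used here, so no gene is called DIF.

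Depth was 8805568 to 16556322 counts per library. The pipeline was tested on simulated data with the same depths and 20439 genes. Of these, 100 changed 2-fold and 100 changed 4-fold in each main comparison. All groups were simulated with the same spread, so the wider replicate spread of dal-2 is absent. Far fewer genes changed than were called in the data. The shares that follow therefore describe the simulation and not the error rates in the data, least of all for dal-2. In the comparison on Dex 30% of the 2-fold and 88% of the 4-fold changes were called, with 12 false among 130 calls; in the dal-2 comparison the shares were 26% and 87%, with 7 false among 120 calls. In the simulated Dex effect in Col-0, where no gene changed, 0 genes were called.

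Alternatives were DESeq2 size factors and upper quartile scaling, no filter and a filter of 5 CPM in 2 libraries, removal of organellar genes, only the libraries of a comparison, a 2-fold minimum, limma-voom, the Wald test of DESeq2 1.42.0, each library left out in turn, and the replicate number as a block. A fit without both dal-2 libraries was added after the data had been seen. When a library is left out, the lone library of its group is assumed to vary like the other groups. For dal-2, whose replicates lay furthest apart, this makes the spread too small. Calls that stay or appear without a dal-2 library therefore count for little. With groups of 2 no sample could be tested as an outlier and no regrouping of samples was counted.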

Results

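Read counts per gene came from RNA sequencing of whole Arabidopsis thaliana seedlings with 4 open true leaves. The 10 libraries form 5 groups of 2: the wild type Col-0 with and without 10 µM dexamethasone (Dex), the line DIF-OX2 with and without Dex, and the mutant dal-2 without Dex. Dex is a synthetic glucocorticoid, used here as the inducer of DIF in the transgenic line DIF-OX2. Col-0 and DIF-OX2 seedlings were 12 days old. The dal-2 libraries came from plants of 20 days (replicate 1) and 21 days (replicate 2) at the same leaf number, so genotype and age cannot be separated in dal-2.

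Counts assigned to genes totalled 9780846 and 10463971 in replicates 1 and 2 of Col-0 and 11384722 and 16556322 in Col-0 on Dex. The totals were 14029728 and 12745229 in DIF-OX2, 8805568 and 14766519 in DIF-OX2 on Dex, and 11316862 and 14894058 in dal-2. Of the 33602 genes in the table, 20681 (61.5%) had enough counts to be tested. Levels are given in CPM, counts scaled to library size, after TMM scaling, as mean ± SD with n = 2. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only spread between these samples, which may be technical. In the fit all 5 groups share the spread of a gene. The dal-2 replicates differed most (SD of log2 replicate differences 0.745, against 0.355 to 0.439 in the other groups). Adjusted p-values can therefore be too small in dal-2 and too large in the other comparisons. A call that ends when 1 library is left out is tested with fewer samples and this shared spread. Its end alone does not show that the change rests on that library. Counting intervals (95%) and the floor of 3 counts over a group, used where a gene had no count, cover counting error only. The 20 most abundant genes held 10.7% to 12.2% of the counts in Col-0, in Col-0 on Dex and in DIF-OX2 without Dex, and 4.83% to 6.47% in DIF-OX2 on Dex and in dal-2. The dal-2 replicates lay further apart than those of any other group: 525 genes differed by more than 4-fold between them, against 24 to 65 genes in the other 4 groups.

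DAL (AT2G33430, also named MORF2), a member of the MORF family of organellar RNA editing factors, is the gene mutated in dal-2 and, by the title of the study, a target of the SCF ubiquitin ligase that contains DIF. Its transcript stood at 29.5 and 35.7 CPM in the dal-2 libraries, below each of the other 8 libraries. Group levels were 103 ± 6.64 CPM in Col-0, 107 ± 10.8 in Col-0 on Dex, 94.1 ± 2.12 in DIF-OX2, 65.9 ± 9.43 in DIF-OX2 on Dex and 32.6 ± 4.35 in dal-2. Against Col-0 it fell by 1.65 on the log2 scale in dal-2 (SE 0.157; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 3.24e-04). In DIF-OX2 on Dex it was lower than in Col-0 on Dex by a log2 fold change of −0.70 (SE 0.153; adjusted p = 0.0144). Dex lowered it within DIF-OX2 (log2 fold change −0.51, adjusted p = 0.0421), while a difference from the Dex effect in Col-0 did not pass the test (difference −0.58, adjusted p = 0.149). The call against Col-0 on Dex ended without replicate 2 of Col-0 on Dex (adjusted p = 0.0977) or of DIF-OX2 on Dex (0.120), and the call within DIF-OX2 ended without replicate 1 or 2 of the uninduced line (0.133 and 0.159) or replicate 2 of the induced one (0.254).

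**Figure D1:**
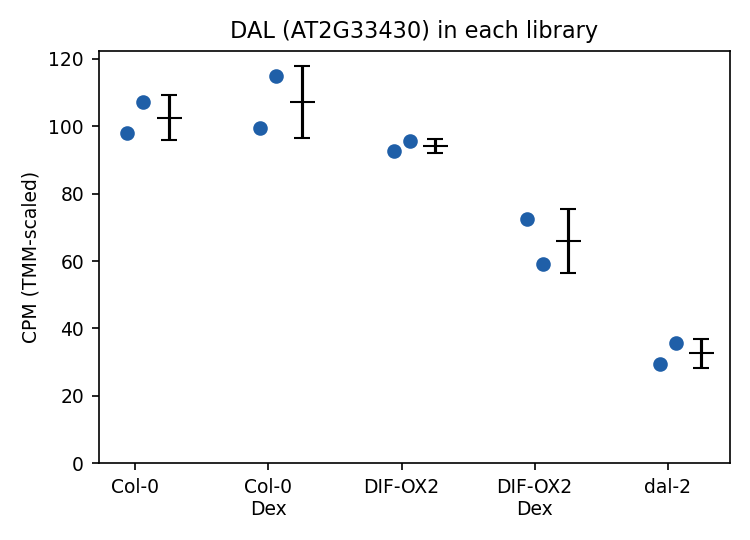
DAL transcript level in each library (points, TMM-scaled CPM on a linear axis from 0), with the mean and SD of each group (bars, n = 2). The dal-2 libraries, at 29.5 and 35.7 CPM, lie below all others, and those of DIF-OX2 on Dex, at 72.6 and 59.3 CPM, lie between dal-2 and the remaining groups.

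DIF-OX2 was compared with Col-0, both on Dex, so that the inducer was present on both sides. That Dex induces DIF in the line is taken from the design and could not be checked, since the sources used here do not give the locus of DIF. Many nuclear genes of photosynthesis fell, and many genes of salicylate defence and of the mitochondrial stress response rose. Of 30 genes for photosystem and electron transport subunits, 24 fell and none rose, with a median log2 fold change of −1.47. Of 16 genes of salicylate signalling and systemic defence, the pathway that limits biotrophic pathogens, 10 rose and none fell, with a median of 1.74. Among all tested genes 4549 changed by edgeR's quasi-likelihood test at an adjusted p of 0.05, 2408 higher and 2141 lower in DIF-OX2, and 2461 of them changed at least 2-fold. The count was 1829, 1648 and 1343 without replicate 1 of Col-0 on Dex, replicate 2 of Col-0 on Dex and replicate 2 of DIF-OX2 on Dex. It was 6892 with only these 4 libraries in the fit and 7065 with both dal-2 libraries left out, a setting chosen after their difference had been seen. The more frequent direction turned with only these 4 libraries (3386 higher and 3506 lower), and by DESeq2 2194 genes were higher and 2195 lower.

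By fitted fold change the 6 highest genes had no count in Col-0 on Dex, so their rank depends on the prior count and only a lower bound of each fold is known. AT1G47980, which the reference describes as a desiccation-like protein, reached 77.1 ± 14.2 CPM, at least 672-fold higher (adjusted p = 5.66e-05). AT4G39610, a MIZU-KUSSEI-like protein, was at least 290-fold higher (adjusted p = 1.82e-04). PSEUDOSRKA, a pseudogene of the self-incompatibility receptor kinase, was at least 249-fold higher, and AT4G11340, a disease resistance protein of the TIR class, at least 245-fold. The berberine-bridge-type enzyme AT1G26390 and the cell wall expansin EXPA19 were at least 216-fold and 194-fold higher. The largest fall was of CYP78A5, a cytochrome P450 that promotes organ growth, which had no count in DIF-OX2 on Dex and 11.0 ± 0.258 CPM in Col-0 on Dex, at least 94.3-fold lower (adjusted p = 9.32e-05). CYP78A5 also had no count in DIF-OX2 without Dex. The aldolase FBA5 fell from 263 ± 18.5 to 12.6 ± 7.93 CPM (log2 fold change −4.41, adjusted p = 0.00102). Also lower were AT5G35777 (log2 fold change −4.92), the thioredoxin-family gene AT3G62950 (−4.23), AT1G13650 (−3.82) and the receptor-like kinase gene AT3G46370 (−3.65). Their adjusted p-values were 0.00216, 0.00895, 0.00139 and 1.65e-04. Of these 12 genes only AT3G62950 lost its call when 1 library was left out, without replicate 2 of Col-0 on Dex (adjusted p = 0.0568) or of DIF-OX2 on Dex (0.101).

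Among 20 nuclear genes for light harvesting proteins, the antenna of both photosystems, 11 fell and none rose, with a median log2 fold change of −1.57; adjusted over the list alone, 15 fell. LHCB2.3 fell from 1895 ± 152 to 342 ± 145 CPM (log2 fold change −2.47, adjusted p = 0.0206) and LHCB1.4 from 2414 ± 535 to 527 ± 153 CPM (−2.20, adjusted p = 0.00677). LHCB1.1 stood at 3002 ± 735 against 7699 ± 581 CPM and did not pass the test (−1.36, adjusted p = 0.320). Members of the LHCB1 and LHCB2 families are near-identical copies, so the split of reads among them is uncertain. The list was lower as a group by camera with a preset correlation (adjusted p = 5.08e-07), but not with an estimated one (adjusted p = 0.474 with an estimated correlation). Within the photosystem list all 30 genes were lower when adjusted over the list alone. PSAN (−1.81, adjusted p = 0.0497), PSBQ2 (−1.73, adjusted p = 0.0119) and PSAD1 (−1.39, adjusted p = 0.00822) are examples, and camera gave adjusted p = 3.69e-12 with the preset and adjusted p = 0.456 with an estimated correlation. Calls ended without any 1 of the 4 libraries for LHCB2.3 (adjusted p = 0.0521 to 0.170) and PSAN (0.130 to 0.262). They ended without replicate 2 of DIF-OX2 on Dex for LHCB1.4 (0.0752), and without replicate 2 of Col-0 on Dex or of DIF-OX2 on Dex for PSBQ2 (0.0660, 0.110) and PSAD1 (0.0572, 0.0824).

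Carbon fixation and chlorophyll synthesis showed the same direction. Of 19 genes of the Calvin-Benson cycle, 5 fell and none rose (median −1.24), with 11 lower when adjusted over the list alone. CP12-2, a regulator of the cycle, fell from 193 ± 15.4 to 60.04 ± 11.5 CPM (log2 fold change −1.68, adjusted p = 0.0190), and GAPA2 by a log2 fold change of −1.45 (adjusted p = 0.0447). RBCS1A, the small subunit of Rubisco, stood at 6616 ± 1660 against 14680 ± 1190 CPM without passing the test (−1.15, adjusted p = 0.105). Of 26 genes of tetrapyrrole and chlorophyll synthesis, 17 fell and 1 rose (median −0.98), with 21 lower and 1 higher when adjusted over the list alone. PORA, a light-dependent protochlorophyllide reductase, had a log2 fold change of −2.66 (adjusted p = 0.0153) and CHLM one of −1.33 (adjusted p = 0.0295). FC1, the ferrochelatase that makes haem, rose (0.63, adjusted p = 0.0137), and HEMA1 did not pass the test (−1.52, adjusted p = 0.0844). Camera called both lists lower (adjusted p = 1.74e-05 and 2.36e-08), with adjusted p = 0.474 and 0.397 with an estimated correlation. Calls ended without any 1 of the 4 libraries for CP12-2 (adjusted p = 0.0597 to 0.153) and GAPA2 (0.0917 to 0.256). Without replicate 1 or 2 of Col-0 on Dex, or replicate 2 of DIF-OX2 on Dex, they ended for FC1 (0.0620, 0.114, 0.102), PORA (0.0622, 0.0865, 0.137) and CHLM (0.0910, 0.127, 0.207).

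Regulators of the chloroplast were tested as well. Of 15 genes of plastid signalling and greening, 4 fell and none rose (median −0.90), and the same number fell when adjusted over the list alone. The sigma factors SIG3 (−1.02, adjusted p = 0.00940) and SIG2 (−0.99, adjusted p = 0.00949) of the plastid RNA polymerase were among them, while GUN1, an integrator of plastid retrograde signals, was not called (−0.37, adjusted p = 0.155). Of 13 nuclear genes for proteins associated with the plastid RNA polymerase, 9 fell and none rose (median −0.72; 12 adjusted over the list alone), among them PTAC14 (−1.02, adjusted p = 0.00413), PTAC7 (−0.99, adjusted p = 0.00250) and PTAC3 (−0.89, adjusted p = 0.0242). Camera gave these lists adjusted p = 0.00580 and 6.70e-06, and adjusted p = 0.474 and 0.397 with an estimated correlation. In the list of DAL and the MORF family, DAL and MORF9 (−0.86, adjusted p = 0.0114) fell and the other 7 of 9 genes were not called, with 2 lower when adjusted over the list alone and camera adjusted p = 0.237. Calls ended without replicate 1 of Col-0 on Dex or replicate 2 of DIF-OX2 on Dex for SIG3 (adjusted p = 0.0566, 0.0870). They also ended without replicate 1 or 2 of Col-0 on Dex, or replicate 2 of DIF-OX2 on Dex, for SIG2 (0.0506, 0.0537, 0.0539), PTAC3 (0.104, 0.0932, 0.0866) and MORF9 (0.0535, 0.0663, 0.0974).

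Genes encoded in the organelles had low counts, 0.0167% to 0.112% of a library for the plastid genome, with the highest shares in Col-0 without Dex. Of 22 plastid genes of photosynthesis, 5 fell and none rose (median −1.20; 5 adjusted over the list alone). They included psbE (−2.03, adjusted p = 0.0396) and psbA, the photosystem II reaction centre protein D1 (−1.84, adjusted p = 0.0320). Camera gave adjusted p = 0.00230, and adjusted p = 0.589 with an estimated correlation. None of 8 plastid NDH genes was called by edgeR, nor when adjusted over the list alone (median −0.89, camera adjusted p = 0.224; ndhJ −0.90, adjusted p = 0.284). Of 21 plastid genes of gene expression, rpoC1 fell (−1.15, adjusted p = 0.0287), and 0 passed when adjusted over the list alone (camera adjusted p = 0.224); matK stood at 1.96 ± 0.278 against 2.23 ± 1.81 CPM (adjusted p = 0.894). The 17 mitochondrial genes had a median of 0.56 with 0 called, over all genes or over the list alone (camera adjusted p = 0.248). Calls ended without any 1 of the 4 libraries for psbE (adjusted p = 0.0671 to 0.228) and psbA (0.110 to 0.169). For rpoC1 they ended without replicate 1 of Col-0 on Dex (0.151), and without replicate 1 or 2 of DIF-OX2 on Dex (0.110, 0.140).

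Most genes of the mitochondrial stress response and of salicylate defence rose, and jasmonate genes moved both ways. Of 12 genes of the mitochondrial dysfunction response, 9 rose and none fell (median 1.21; 12 adjusted over the list alone). The alternative oxidase AOX1D rose from 0.163 ± 0.0378 to 5.25 ± 1.33 CPM (log2 fold change 4.97, adjusted p = 0.00221), AT12CYS-2 by 4.19 (adjusted p = 0.00370) and AOX1A by 0.87 (adjusted p = 0.00369). Camera called this list and the salicylate list higher (adjusted p = 1.21e-07 and 4.25e-08), with adjusted p = 0.254 for each with an estimated correlation. SARD1, a transcription factor of salicylate synthesis, rose from 1.204 ± 0.898 to 82.1 ± 14.3 CPM (6.0, adjusted p = 2.32e-04). The pathogenesis marker PR1 was higher by a count ratio of 210 (95% interval 57.8 to 1740; adjusted p = 0.0457). Adjusted over the list alone, 12 salicylate genes were higher and 1 lower. Of 22 jasmonate genes, 7 rose and 2 fell (8 and 2 adjusted over the list alone; median 0.25). The defensin PDF1.2 was at least 79.7-fold higher and the repressor JAZ8 at least 20.9-fold higher (adjusted p = 0.00143 and 0.00819). VSP2 (−1.88, adjusted p = 0.0188) and the allene oxide synthase AOS (−0.94, adjusted p = 0.00376) fell, and LOX2 was not called (0.24, adjusted p = 0.633). Camera gave the jasmonate list adjusted p = 0.0115, and adjusted p = 0.397 with an estimated correlation. PR1 lay at 21.2 and 14.1 CPM in the libraries of DIF-OX2 on Dex and at 0.0949 and 0.0681 CPM in those of Col-0 on Dex. Its spread in the fit is shared with dal-2, where the replicates lay at 42.9 and 0.389 CPM. The call of PR1 ended without any 1 of the 4 libraries. That of JAZ8 ended without replicate 2 of Col-0 on Dex or of DIF-OX2 on Dex (0.0630, 0.0651), and that of VSP2 without replicate 1 or 2 of Col-0 on Dex or replicate 1 of DIF-OX2 on Dex (0.0738, 0.0856, 0.0686).

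Other stress lists were mixed. Of 11 oxidative stress genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone; median 0.18, camera adjusted p = 0.0525). BAP1 (2.55, adjusted p = 0.00573) and the zinc finger genes ZAT10 (2.32, adjusted p = 0.00363) and ZAT12 (1.61, adjusted p = 0.00281) rose, and the plastid superoxide dismutase FSD1 fell (−1.03, adjusted p = 0.0225). Of 10 genes of heat shock and protein folding, 3 rose (5 adjusted over the list alone), with BIP3 at 2.15 (adjusted p = 0.0295) and DREB2A at 1.74 (adjusted p = 0.0213); HSP101 was not called (1.08, adjusted p = 0.0622). The heat list had a median of 1.80 and camera adjusted p = 0.0164, with adjusted p = 0.470 with an estimated correlation. Of 14 genes of carbon starvation and senescence, 3 rose, as when adjusted over the list alone (median 0.23, camera adjusted p = 0.0652). The senescence marker SAG13 was higher by a count ratio of 381 (95% interval 130 to 1850; adjusted p = 3.93e-04). The beta-glucosidase DIN2 rose from 1.32 ± 0.255 to 21.4 ± 5.08 CPM (adjusted p = 0.00232), and ASN1 was not called (0.41, adjusted p = 0.860). Of 13 genes of anthocyanin and flavonoid synthesis, UF3GT rose (0.89, adjusted p = 0.0305) and 0 passed when adjusted over the list alone. Chalcone synthase CHS was not called (0.68, adjusted p = 0.189). The list's median was 0.79 with camera adjusted p = 0.0260, adjusted p = 0.590 with an estimated correlation, and adjusted p = 0.0501 and 0.0772 without replicate 2 of Col-0 on Dex and replicate 1 of DIF-OX2 on Dex. Calls ended without any 1 of the 4 libraries for UF3GT (0.114 to 0.147) and DREB2A (0.0624 to 0.138), and without replicate 2 of Col-0 on Dex for BAP1 (0.0537). For FSD1 (0.0722, 0.125, 0.167) and BIP3 (0.0672, 0.202, 0.279) they ended without replicate 1 or 2 of Col-0 on Dex or replicate 2 of DIF-OX2 on Dex.

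Developmental markers also differed. Of 10 stomatal lineage and trichome markers, 3 fell and 1 rose (5 and 1 adjusted over the list alone; median −0.96). GL1 (−3.85, adjusted p = 0.00156) and GL2 (−1.51, adjusted p = 0.00268), transcription factors of trichome formation, fell. SPCH, which starts the stomatal lineage, rose from 6.38 ± 0.0328 to 28.3 ± 3.33 CPM (2.15, adjusted p = 0.00119), and TMM was not called (−0.58, adjusted p = 0.115). Of 9 genes of flowering and phase change, 4 fell and none rose (6 adjusted over the list alone; median −1.43). SPL9, which promotes the adult phase, fell by 1.98 on the log2 scale (adjusted p = 0.00461), and SPL3 by a count ratio of 0.128 (95% interval 0.0246 to 0.423; adjusted p = 0.0263). FT was at 0.583 ± 0.395 against 0.387 ± 0.258 CPM (adjusted p = 0.718). Camera called both lists lower (adjusted p = 0.0276 and 0.00413), with adjusted p = 0.397 for each with an estimated correlation. Of 14 root markers, which also stand for the share of root in a whole seedling, 3 rose, as when adjusted over the list alone (median 0.37, camera adjusted p = 0.328), among them PHO1 (0.87, adjusted p = 0.0194) and LRX1 (0.76, adjusted p = 0.0106); PIN2 was not called (0.48, adjusted p = 0.162). None of 9 markers of dividing cells was called, nor when adjusted over the list alone (median −0.29, camera adjusted p = 0.124; CYCB1;1 −0.18, adjusted p = 0.821). Of 11 clock genes, which mark the hour of harvest, GI rose (1.67, adjusted p = 0.0402), 0 passed when adjusted over the list alone, and CCA1 was not called (−0.72, adjusted p = 0.664; camera adjusted p = 0.768). Of the seed storage genes 2 were tested, too few for a list test, and 0 was called (CRU1, adjusted p = 0.201, and adjusted p = 0.0328 without replicate 1 of DIF-OX2 on Dex). The call of GI ended without any 1 of the 4 libraries (adjusted p = 0.0969 to 0.213) and that of SPL9 without replicate 2 of DIF-OX2 on Dex (0.0576). Calls of SPL3 (0.0919, 0.0976, 0.231), PHO1 (0.0981, 0.130, 0.153) and LRX1 (0.0848, 0.0660, 0.0941) ended without replicate 1 or 2 of Col-0 on Dex or replicate 2 of DIF-OX2 on Dex.

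Camera called 14 of 23 lists in this comparison, 5 higher and 9 lower, and 0 with an estimated correlation, for which the lowest adjusted p was 0.254. By limma's fry, which asks whether a list moves one way or in either direction without setting it against other genes, 10 and 16 lists passed. Of 63 genes named here and called in this comparison, 28 kept the call without each of the 4 libraries in turn.

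**Figure D2:**
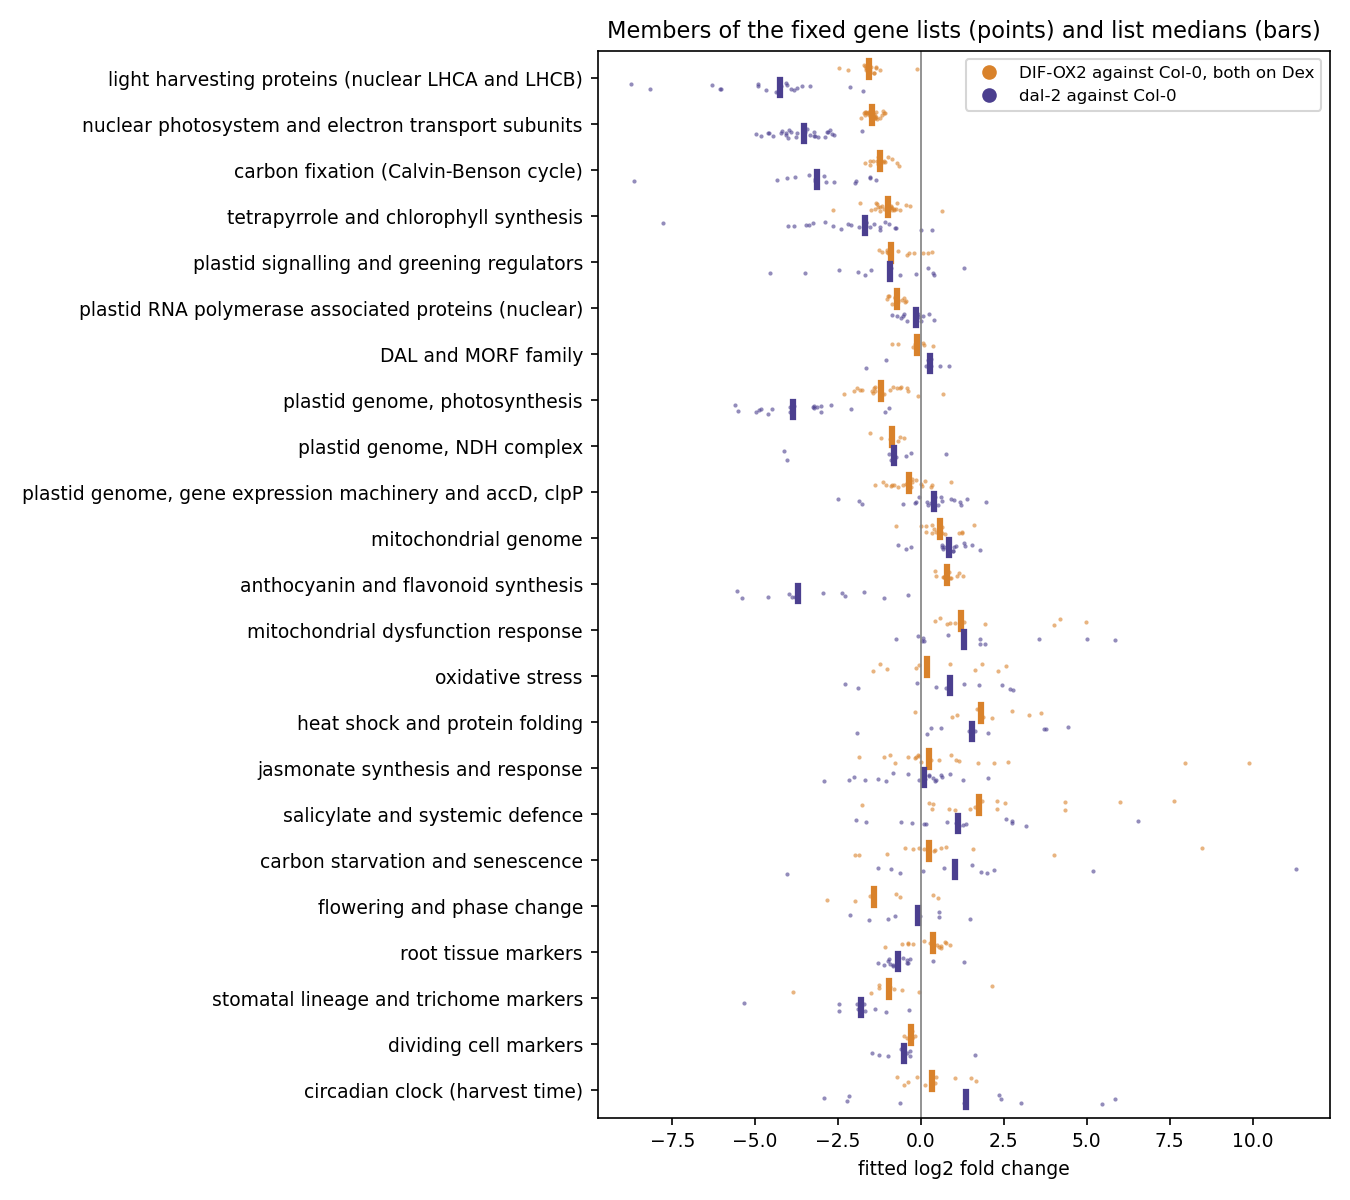
Fitted log2 fold change (x axis) of each tested member (points) of the fixed gene lists (y axis), with list medians (bars), for DIF-OX2 against Col-0 on Dex (orange) and dal-2 against Col-0 (purple). Medians of the light harvesting list are −1.57 and −4.26 and those of the anthocyanin list 0.79 and −3.70; points of genes with no count in 1 group depend on the prior count and are not bounds.

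The mutant dal-2, whose plants were also older, was compared with Col-0, both without Dex. Some clock genes, which mark the hour of harvest, also differed from Col-0 in both dal-2 libraries. GI stood at 158.8 and 45.36 CPM in replicates 1 and 2 of dal-2, against 20.72 and 19.52 CPM in Col-0. PRR7 stood at 161.8 and 222.1 against 71.29 and 83.58 CPM. PRR9 in replicate 2 of dal-2 (21.04 CPM) lay within the Col-0 values (23.62 and 12.94 CPM). An hour of harvest that differed from Col-0 therefore stays open for the changes below, beside genotype and age. Every tested gene of light harvesting, photosystem and electron transport subunits and carbon fixation fell, and nearly all genes of anthocyanin synthesis were lower as well. The 20 light harvesting genes had a median log2 fold change of −4.26, the 30 photosystem genes −3.53 and the 19 carbon fixation genes −3.14. With replicate 1 and replicate 2 of dal-2 alone the photosystem median was −4.39 and −3.17 and the carbon fixation median −4.18 and −2.52. Of 13 anthocyanin and flavonoid genes 11 fell (median −3.70). Among all tested genes 7011 changed by edgeR's quasi-likelihood test at an adjusted p of 0.05, 3280 higher and 3731 lower in dal-2, and 3976 changed at least 2-fold. The share of higher genes was 46.8%; with upper quartile scaling 7704 genes changed, 4564 higher and 3140 lower (59.2% higher), and the median log2 fold change of all genes moved from 0.03 to 0.16. With a filter of 5 CPM more genes were higher as well (3504 higher and 3031 lower). The count was 3913 and 3891 without replicate 1 and 2 of Col-0, and 2258 with only these 4 libraries in the fit.

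Among the highest genes by fitted fold change was M17, a late embryogenesis abundant protein of desiccation tolerance, at least 359-fold higher (adjusted p = 0.0110), with 6.01 CPM in replicate 1 of dal-2 and 102 CPM in replicate 2. SAG13 had no count in Col-0 and was at least 160-fold higher (adjusted p = 4.20e-04). The nucleoside triphosphate hydrolase gene AT4G05380 was at least 108-fold higher, and AT5G53230, AT1G30170 and AT5G53240, which encode related proteins of unknown function, at least 124-fold, 95.3-fold and 85.1-fold. Genes with low fitted fold changes included AT2G16367, a defensin-like gene with no count in dal-2 (at least 191-fold lower, adjusted p = 0.00430), whose rank depends on the prior count, and the thionin AT1G66100 (381 ± 2.90 to 0.457 ± 0.453 CPM; log2 fold change −9.60, adjusted p = 6.70e-05). IRT1, the iron transporter of the root epidermis, fell from 152 ± 45.2 to 0.226 ± 0.163 CPM (−9.40, adjusted p = 9.03e-05). CYP82C4, a P450 of the iron deficiency response, was lower by a count ratio of 7.76e-04 (95% interval 1.60e-04 to 0.00227; adjusted p = 1.26e-05). AT4G13575 was lower by a count ratio of 9.37e-04 (2.37e-05 to 0.00524), and AT1G13650 had a log2 fold change of −9.80 (adjusted p = 1.35e-04). Of these 12 genes, M17 and AT5G53240 lost their calls with only the libraries of this comparison in the fit.

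In the light harvesting list all 20 genes fell, also when adjusted over the list alone. LHCB2.3 fell from 1655 ± 243 to 3.77 ± 3.78 CPM (log2 fold change −8.75, adjusted p = 2.87e-04) and LHCB1.4 by a log2 fold change of −8.16 (adjusted p = 9.19e-05). LHCB1.1 fell as well (−6.03, adjusted p = 0.00476), with 13.8 CPM in replicate 1 of dal-2 and 208 CPM in replicate 2. The list's median was −5.38 with replicate 1 of dal-2 alone and −3.52 with replicate 2 alone. All 30 photosystem genes fell, also over the list alone, among them plastocyanin PETE1 (258 ± 29.3 to 8.12 ± 6.27 CPM, adjusted p = 3.98e-04), PSAH2 (−4.84, adjusted p = 1.41e-04) and PSAD1 (−4.0, adjusted p = 1.42e-04). All 19 carbon fixation genes fell, over all genes and over the list alone. The Rubisco small subunit genes RBCS2B (3472 ± 74.4 to 8.52 ± 7.03 CPM, adjusted p = 1.80e-04), RBCS3B (adjusted p = 0.0121) and RBCS1A (13400 ± 203 to 1525 ± 993 CPM, adjusted p = 0.00231) are examples, and their reads may be split uncertainly among near-identical copies. Camera gave adjusted p = 6.07e-25, 1.44e-38 and 1.27e-15 for these lists, with adjusted p = 0.217, 0.217 and 0.224 with an estimated correlation.

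Tetrapyrrole synthesis and its regulators were also lower. Of 26 tetrapyrrole and chlorophyll genes 24 fell and none rose (24 and 1 adjusted over the list alone; median −1.68). PORA had no count in dal-2 (at least 23.9-fold lower, adjusted p = 0.00224). CAO, which makes chlorophyll b, fell from 576 ± 22.5 to 35.4 ± 33.7 CPM (−4.02, adjusted p = 0.00257), and HEMA1, which makes glutamyl-tRNA reductase, by 2.90 on the log2 scale (adjusted p = 0.00695). Of 15 genes of plastid signalling and greening 10 fell and 1 rose (10 and 2 adjusted over the list alone; median −0.94). The greening factors GLK1 (−4.55, adjusted p = 3.51e-04) and GLK2 (−3.49, adjusted p = 0.00169) fell, as did GUN1 (−0.64, adjusted p = 0.0230), and the organellar RNA polymerase RPOTMP rose (1.3, adjusted p = 0.0213). Camera gave adjusted p = 9.96e-17 and 0.00273 for these lists, with adjusted p = 0.217 and 0.467 with an estimated correlation. Of 13 genes associated with the plastid RNA polymerase 3 fell and none rose, also over the list alone (median −0.16, camera adjusted p = 0.302), with PTAC7 at −0.89 (adjusted p = 0.00244) and TRXZ at −0.73 (adjusted p = 0.00666); PTAC3 was not called (−0.43, adjusted p = 0.164). In the DAL and MORF list DAL and MORF9 fell (MORF9 −1.05, adjusted p = 0.00348), also over the list alone, while the list's median of 0.26 and its mean of −0.00369 differed in sign (camera adjusted p = 0.888). Calls ended without replicate 1 or 2 of Col-0 for GUN1 (adjusted p = 0.112, 0.105) and RPOTMP (0.0518, 0.110), and for RPOTMP also without replicate 1 of dal-2 (0.0605).

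Of 22 plastid genes of photosynthesis 19 fell and none rose (20 adjusted over the list alone; median −3.84, with −4.45 and −3.36 in replicate 1 and replicate 2 alone). psbA fell from 315 ± 204 to 6.40 ± 4.13 CPM (−5.60, adjusted p = 4.76e-04), and psbI was lower by a count ratio of 0.0189 (95% interval 0.00224 to 0.0715). The size of these falls depends on the control: psbA stood at 89.1 ± 3.65 CPM in Col-0 on Dex and 92.9 ± 11.5 in DIF-OX2 without Dex, and the list had medians of −1.50 and −1.30 in these groups against Col-0 without Dex. Camera gave adjusted p = 1.62e-14, and adjusted p = 0.224 with an estimated correlation. Plastid genes took 0.0516% and 0.112% of the counts in Col-0 and 0.0169% and 0.0305% in dal-2. Of 8 NDH genes ndhK (−4.12, adjusted p = 0.00654) and ndhJ (−4.05, adjusted p = 0.00178) fell, also over the list alone (median −0.83, camera adjusted p = 0.173; −1.93 and −0.55 with replicate 1 and replicate 2 alone). The level of ndhJ was 2.67 ± 1.1 CPM in Col-0, 0.991 ± 0.342 in Col-0 on Dex and 0.145 ± 0.109 in dal-2. Of 21 plastid genes of gene expression, clpP rose (1.95, adjusted p = 0.0103) and rps14 (−2.52, adjusted p = 0.0120) and matK (−1.79, adjusted p = 0.0413) fell. In Col-0, Col-0 on Dex, DIF-OX2 without Dex and dal-2, matK stood at 6.87 ± 2.94, 2.23 ± 1.81, 2.89 ± 0.615 and 1.95 ± 0.928 CPM and rps14 at 7.20 ± 3.09, 3.33 ± 1.33, 3.47 ± 0.460 and 1.22 ± 0.949 CPM. Adjusted over the list alone, 1 was higher and 1 lower (median 0.39, camera adjusted p = 0.456), and the median turned from 0.70 with replicate 2 of dal-2 alone to −0.19 with replicate 1 alone. Of 17 mitochondrial genes 2 rose, ATMG00060 (1.79, adjusted p = 0.0333) and ATMG01360 (1.32, adjusted p = 0.0293), and 0 passed when adjusted over the list alone (median 0.85, camera adjusted p = 0.100). With replicate 2 of dal-2 alone the mitochondrial median was 1.47 with 10 genes higher, and with replicate 1 alone it was 0.30 with 0 higher and 1 lower. Calls ended without replicate 1 of Col-0 for clpP (adjusted p = 0.0584), without replicate 2 of Col-0 for rps14 (0.0821), and without replicate 1 or 2 of Col-0 or replicate 1 of dal-2 for matK (0.0572, 0.240, 0.0932). They ended without replicate 1 or 2 of Col-0 or replicate 2 of dal-2 for ATMG00060 (0.0962, 0.154, 0.136) and ATMG01360 (0.134, 0.0640, 0.120).

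In the anthocyanin list LDOX fell from 50.3 ± 12.8 to 1.04 ± 0.411 CPM (−5.55, adjusted p = 1.05e-04) and DFR by 5.38 on the log2 scale (adjusted p = 7.74e-05), both late enzymes of anthocyanin synthesis. CHS fell by 1.13 (adjusted p = 0.0350). Adjusted over the list alone 12 of the 13 genes were lower, and camera gave adjusted p = 5.06e-14, with adjusted p = 0.217 with an estimated correlation. Of 12 genes of the mitochondrial dysfunction response 6 rose and 1 fell, also over the list alone (median 1.3; camera adjusted p = 0.00262, with adjusted p = 0.224 with an estimated correlation). UPOX rose from 1.53 ± 0.585 to 49.1 ± 15.8 CPM (4.99, adjusted p = 1.19e-04), AOX1A rose by 0.82 (adjusted p = 0.00299), and AOX1D was at least 3.35-fold higher (adjusted p = 0.0227). GSTU25 fell (−0.76, adjusted p = 0.00703). Of 11 oxidative stress genes 6 rose and 2 fell, also over the list alone (median 0.86). The superoxide dismutase CSD1 rose from 63.3 ± 5.79 to 432 ± 95.7 CPM (2.77, adjusted p = 1.85e-04), as did the catalase CAT3 (2.67, adjusted p = 0.00109) and ZAT12 (0.74, adjusted p = 0.0420). CAT2 (−2.30, adjusted p = 0.0390) and FSD1 (−1.91, adjusted p = 0.00135) fell. The dal-2 replicates differed in both catalases, in opposite directions. CAT2 stood at 120 CPM in replicate 1 and 867 CPM in replicate 2, and CAT3 at 4230 and 2495 CPM. Camera gave the oxidative list adjusted p = 0.00300, adjusted p = 0.228 with an estimated correlation, and adjusted p = 0.151 without replicate 2 of dal-2. Calls ended without any 1 of the 4 libraries for ZAT12 (0.0533 to 0.137), and without replicate 1 or 2 of Col-0 for AOX1D (0.0785, 0.0830) and CAT2 (0.114, 0.100). For GSTU25 the call ended without replicate 1 of Col-0 (0.0733), and for CHS without replicate 1 of Col-0 (0.251) or of dal-2 (0.0967).

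Defence and senescence lists went both ways in dal-2. Of 16 salicylate genes 6 rose and 3 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.185). PR1 rose (6.55, adjusted p = 0.0401), with 42.9 CPM in replicate 1 of dal-2 and 0.389 CPM in replicate 2. PR2 rose from 0.825 ± 0.251 to 7.48 ± 6.41 CPM (adjusted p = 0.0101), and ALD1 (−1.97, adjusted p = 0.0321) and WRKY70 (−1.65, adjusted p = 0.00282) fell. Of 22 jasmonate genes 1 rose and 4 fell, also over the list alone; the median of 0.08 and the mean of −0.23 differed in sign (camera adjusted p = 0.394). VSP1 rose (1.26, adjusted p = 0.0195), and AOS (−2.93, adjusted p = 6.70e-05) and LOX2 (−2.16, adjusted p = 0.00241) fell. Of 14 starvation and senescence genes 5 rose and 3 fell (6 and 3 adjusted over the list alone; median 1.02, camera adjusted p = 0.0968). DIN2 rose by 5.2 (adjusted p = 8.71e-04), the sugar transporter SWEET15 fell from 28.6 ± 7.63 to 1.65 ± 1.66 CPM (adjusted p = 0.00198), and PAO, which degrades chlorophyll, fell (−0.91, adjusted p = 0.00310); ASN1 was not called (1.00, adjusted p = 0.583). Of 10 heat shock genes DREB2A rose (2.03, adjusted p = 0.0124) and the plastid chaperone CLPB3 fell (−1.94, adjusted p = 0.00291), also over the list alone (median 1.55, camera adjusted p = 0.353), while HSP101 was not called (0.18, adjusted p = 0.714). With replicate 1 of dal-2 alone, the medians of the starvation and heat lists were −0.73 and −0.74, and with replicate 2 alone 1.62 and 1.43. Calls ended without replicate 1 or 2 of Col-0 for PR1 (adjusted p = 0.152, 0.158) and DREB2A (0.0702, 0.0562), and for PR1 also without replicate 1 of dal-2 (0.565). They ended without replicate 2 of Col-0 for PR2 (0.0659), without replicate 2 of Col-0 or of dal-2 for VSP1 (0.105, 0.0508), and without replicate 1 or 2 of Col-0 or replicate 2 of dal-2 for ALD1 (0.187, 0.0736, 0.0977).

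Of 10 stomatal and trichome markers 7 fell and none rose in dal-2, also over the list alone (median −1.81). GL1 was lower by a count ratio of 0.0221 (95% interval 0.00445 to 0.0669), and EPF1 (−2.49, adjusted p = 0.00593) and TMM (−1.69, adjusted p = 0.00201) fell. Camera gave adjusted p = 1.09e-05, and adjusted p = 0.217 with an estimated correlation. Of 14 root markers 7 fell and 1 rose, also over the list alone (median −0.68). The endodermal gene CASP2 (−1.11, adjusted p = 0.00294) fell, the glucosidase PYK10 rose from 1986 ± 45.1 to 4875 ± 371 CPM (1.3, adjusted p = 0.00231), and PIN2 was not called (−0.38, adjusted p = 0.232). Of 9 markers of dividing cells 4 fell and 1 rose (5 and 1 adjusted over the list alone; median −0.52). KNOLLE (−1.47, adjusted p = 0.00168) and AUR1 (−1.27, adjusted p = 0.00111) fell, while CYCB1;1 rose from 8.18 ± 1.19 to 25.5 ± 18.3 CPM (adjusted p = 0.0252). Camera gave the root and dividing cell lists adjusted p = 0.0424 each, with adjusted p = 0.648 each with an estimated correlation. The root call ended without replicate 1 of Col-0 (adjusted p = 0.102) or replicate 2 of dal-2 (0.412), and that of dividing cells without replicate 1 or 2 of Col-0 (0.0546, 0.0575) or replicate 2 of dal-2 (0.617). Of 9 genes of flowering and phase change 4 fell and 1 rose, also over the list alone (median −0.11, camera adjusted p = 0.357): SPL5 (−2.15, adjusted p = 0.0162) and SPL15 (−1.57, adjusted p = 0.00673) fell and FUL rose (1.47, adjusted p = 0.0370), with FT not called (0.54, adjusted p = 0.602). The seed storage genes CRU1 and CRU3 had no count in Col-0 and were at least 12.7-fold and 5.77-fold higher in dal-2 (adjusted p = 0.0356 and 0.0189). Calls ended without replicate 1 of Col-0 for SPL15 (0.0506), without replicate 2 of Col-0 for SPL5 (0.116), and without replicate 1 or 2 of Col-0 for CYCB1;1 (0.0785, 0.116) and CRU3 (0.0702, 0.0726). They ended without replicate 1 or 2 of Col-0 or replicate 2 of dal-2 for FUL (0.0640, 0.181, 0.0580) and CRU1 (0.112, 0.117, 0.0635).

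Of 11 clock genes 7 rose in dal-2 and none fell, also over the list alone (median 1.36, camera adjusted p = 0.173), but the replicates disagreed. The evening gene ELF4 stood at 90.4 CPM in replicate 1 of dal-2 and 0.278 CPM in replicate 2, against 0.773 ± 0.483 CPM in Col-0 (log2 fold change 5.86, adjusted p = 0.0487). Without replicate 1 of dal-2 its log2 fold change was −1.44 (adjusted p = 0.180), and that of PRR5 went from 5.46 (adjusted p = 0.0276) to 0.96 (adjusted p = 0.135). CCA1, a morning gene, was at 4.845 and 155 CPM in these libraries against 379 ± 41.6 CPM in Col-0 (−2.24, adjusted p = 0.140). With replicate 1 or 2 of dal-2 left out its log2 fold change was −1.30 and −6.30. The calls of ELF4 (0.156, 0.192) and PRR5 (0.113, 0.132) also ended without replicate 1 or 2 of Col-0.

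**Figure D3:**
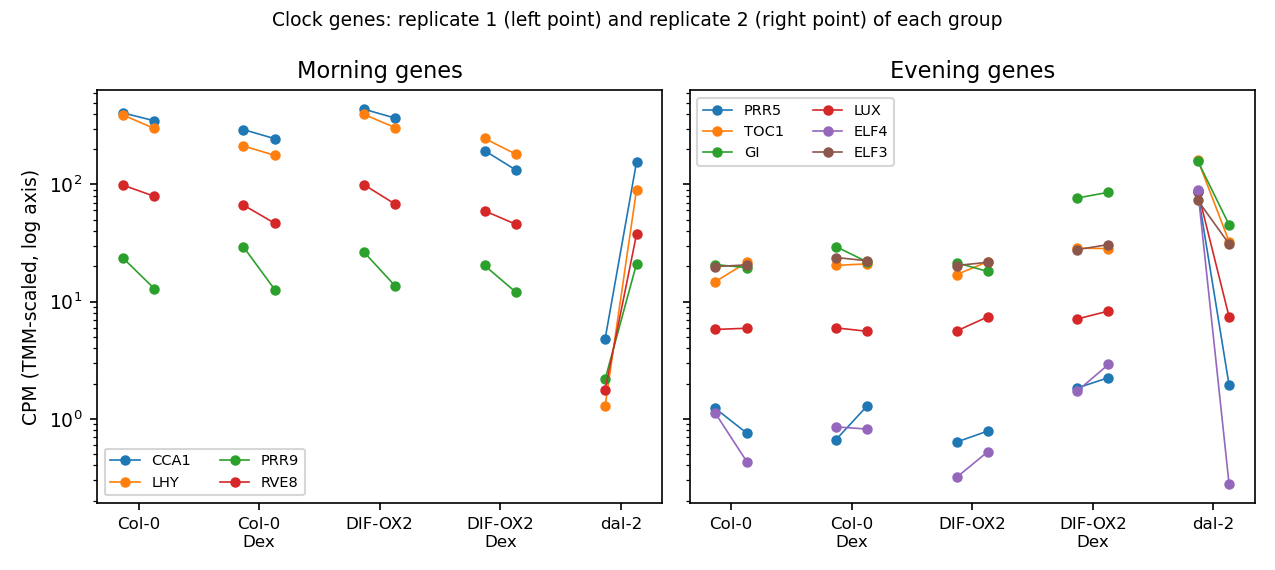
Level of 4 morning and 6 evening clock genes (TMM-scaled CPM, log axis) in replicate 1 (left point) and replicate 2 (right point) of each group, joined by a line. Only in dal-2 do the replicates lie far apart, as for CCA1 (4.845 and 155 CPM) and ELF4 (90.4 and 0.278 CPM).

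Camera called 12 of 23 lists in dal-2, 2 higher and 10 lower, and 0 with an estimated correlation, for which the lowest adjusted p was 0.217. With an estimated correlation it called 0 lists in each of the 6 comparisons, even where every tested light harvesting gene fell. Its lack of a call therefore cannot tell changed lists from unchanged ones here. By fry 14 lists moved one way and 22 changed in either direction. Of the genes named, 87 were called in dal-2. Leaving out a dal-2 library does not test these calls, because the other library then takes its spread from groups with closer replicates.

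Both main comparisons share no library, so their fold changes were compared across the 20681 tested genes, which are not independent replicates. SAG13 rose in both, and so did the plastid glucose-6-phosphate transporter GPT2, which increased from 0.184 ± 0.126 to 49.0 ± 19.9 CPM in DIF-OX2 on Dex and was at least 16.4-fold higher in dal-2. The berberine-bridge-type enzyme AT1G26410 was higher by a count ratio of 233 in DIF-OX2 (95% interval 41.4 to 9246) and at least 6.70-fold in dal-2. PR1 was called higher in both, but its rise in dal-2 rests on replicate 1 (42.9 CPM, against 0.389 in replicate 2 and 0.219 ± 0.00502 in Col-0). AT5G35777 fell in both (log2 fold change −4.92 and −5.77), as did the glutaredoxin AT3G21460 (−4.55, and at least 56.1-fold lower in dal-2). The glycosyltransferase AT4G27570 (count ratios 0.0306 and 0.0190) and the salt stress factor NIG1 (0.0370 and 0.0147) fell in both as well. The fold changes correlated with Pearson's r = 0.515 and Spearman's rho = 0.519 (covariance 0.641). Shared rises numbered 1068, against 382 for independent lists, and shared falls 1472, against 386. Of 2719 genes called in both, 2540 (93.4%) changed in the same direction; 118 rose in DIF-OX2 and fell in dal-2, and 61 the reverse, against 434 and 340 for independent lists. Shared falls were larger in dal-2 for 1109 of 1472 genes, and shared rises for 484 of 1068. Shared rises numbered 659 and 639 without replicate 1 and 2 of Col-0, 523 without either replicate of Col-0 on Dex, and 458 without replicate 2 of DIF-OX2 on Dex. Shared falls numbered 583 and 521 without replicate 1 and 2 of Col-0 on Dex, 365 without replicate 2 of DIF-OX2 on Dex and 2335 without replicate 2 of dal-2. In DIF-OX2 on Dex, calls ended for AT1G26410 without replicate 2 of Col-0 on Dex (adjusted p = 0.0587), for AT4G27570 without replicate 2 of DIF-OX2 on Dex (0.0553), and for NIG1 without replicate 1 or 2 of Col-0 on Dex or replicate 2 of DIF-OX2 on Dex (0.0826, 0.101, 0.203). In dal-2 they ended for AT1G26410 without replicate 1 or 2 of Col-0 or replicate 1 of dal-2 (0.112, 0.117, 0.0940) and for NIG1 without replicate 1 of Col-0 (0.0576).

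**Figure D4:**
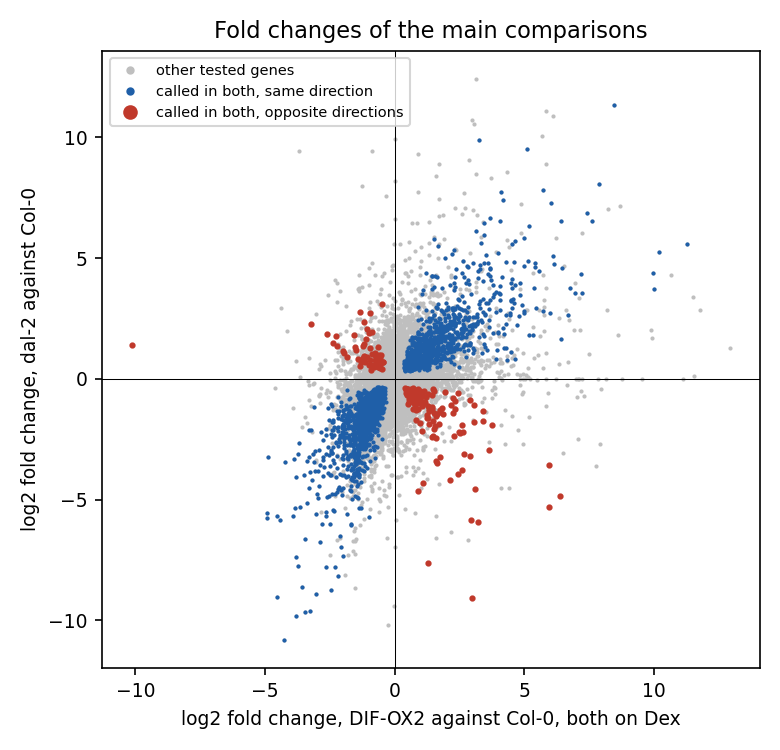
Fitted log2 fold change of each tested gene in DIF-OX2 against Col-0 on Dex (x axis) and in dal-2 against Col-0 (y axis). Of the genes called in both comparisons, 2540 changed in the same direction (blue) and 118 and 61 in opposite directions (red); the values of genes with no count in 1 group depend on the prior count.

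The difference between both effects was tested as well, dal-2 minus DIF-OX2 on Dex. Each effect was taken against its own Col-0 control, so a difference between both controls enters it. Plastid photosynthesis genes had a lower median in Col-0 on Dex than in Col-0 (psbA 89.1 ± 3.65 against 315 ± 204 CPM). Part of their difference given below can therefore come from the controls. The test passed for 1255 genes by edgeR, 391 higher and 864 lower in dal-2. Anthocyanin genes had a median difference of −4.58, with 7 of 13 genes differing (camera adjusted p = 1.64e-31, with adjusted p = 0.201 with an estimated correlation). In the light harvesting list 9 of 20 genes differed (median −2.73; camera adjusted p = 1.65e-20, with adjusted p = 0.332 with an estimated correlation), in the photosystem list 14 of 30 (median −2.09; adjusted p = 8.30e-23, with adjusted p = 0.332 with an estimated correlation), and among photosynthesis genes of the plastid genome 5 of 22 (median −2.41; adjusted p = 2.19e-09, with adjusted p = 0.396 with an estimated correlation). Genes for proteins associated with the plastid RNA polymerase lay the other way, higher in dal-2 than in DIF-OX2 on Dex (median 0.47; 1 of 13 genes; adjusted p = 0.00202, with adjusted p = 0.458 with an estimated correlation). Root markers differed by a median of −0.97 (5 of 14 genes; adjusted p = 7.65e-04, with adjusted p = 0.458 with an estimated correlation), and salicylate genes by −0.93 (3 of 16 genes; adjusted p = 4.83e-04, with adjusted p = 0.332 with an estimated correlation).

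Within DIF-OX2, seedlings on Dex were compared with seedlings without it. The triterpene synthase PEN3 (AT5G36150) rose from 0.0833 ± 0.00588 to 333 ± 69.6 CPM, a count ratio of 4168 (95% interval 1154 to 34420; adjusted p = 5.03e-05). The defensin PDF1.3 was at least 282-fold higher, AT4G39610 at least 277-fold and AT4G11340 at least 233-fold; reads of PDF1.3 may be shared with its close copies. FBA5 (−4.58, adjusted p = 7.81e-04), AT5G35777 (−5.33, adjusted p = 0.00144), AT3G62950 (−4.26, adjusted p = 0.00832) and AT1G13650 (−4.18, adjusted p = 9.02e-04) fell. Photosystem genes fell in 25 of 30 cases (29 adjusted over the list alone; median −1.41) and 11 of 16 salicylate genes rose (13 over the list alone; median 2.08). Of 13 anthocyanin genes 6 rose (7 over the list alone, median 1.2). Some started from a lower level in uninduced DIF-OX2 than in Col-0, as LDOX (29.9 ± 10 against 50.3 ± 12.8 CPM) and DFR (37.0 ± 4.8 against 61.9 ± 2.58). CHS did not (329 ± 100 against 338 ± 134 CPM). Camera gave the photosystem, salicylate and anthocyanin lists adjusted p = 1.27e-10, 3.23e-08 and 0.00102, with adjusted p = 0.432, 0.259 and 0.432 with an estimated correlation. In all 5023 genes changed by edgeR, 2632 higher and 2391 lower, 2698 of them at least 2-fold. The more frequent direction turned by DESeq2 (2425 higher and 2494 lower) and with only the libraries of this comparison (3394 and 3492). Camera called 14 lists, with 0 called with an estimated correlation (lowest adjusted p = 0.259). The count was 2002 and 2014 without replicate 1 and 2 of uninduced DIF-OX2, 1394 without replicate 2 of DIF-OX2 on Dex and 7632 with both dal-2 libraries left out; the call of AT3G62950 ended without replicate 2 of DIF-OX2 on Dex (adjusted p = 0.0944).

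In Col-0, which shows the effect of Dex without the transgene, no single gene passed, while plastid genes had lower medians. The 22 plastid genes of photosynthesis had a median log2 fold change of −1.50, with 0 called over all genes and 20 lower when adjusted over the list alone. Plastid genes took 0.0516% and 0.112% of the counts in Col-0 without Dex and 0.0365% and 0.0288% with it. The same 22 genes had a median of −1.30 in DIF-OX2 without Dex against Col-0 without Dex, where 10 were lower over the list alone. Tetrapyrrole genes had a median of 0.19 and oxidative stress genes one of 0.20, with 0 called in either. The number of changed genes was 0 by edgeR, with 566 at an unadjusted p under 0.05 against 1034 by chance, and 0 by DESeq2 and by limma-voom. Camera called 10 lists with the preset correlation, 4 higher and 6 lower (plastid photosynthesis adjusted p = 2.00e-45), and 0 with an estimated one (lowest adjusted p = 0.241), and fry called 0.

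Whether Dex acted differently in the line and in Col-0 was tested as an interaction. CYS2, a phytocystatin that inhibits cysteine proteases, was at 1.64 and 0.727 CPM in Col-0 without and with Dex and at 1.04 and 735 CPM in DIF-OX2 (adjusted p = 0.0102). The homeodomain-like gene AT3G10590 was at 0.218, 0.333, 0.167 and 52.4 CPM in the same order (adjusted p = 0.0109). AT1G47980 (0.110, 0, 0.0396 and 77.1 CPM; adjusted p = 0.0184) and PSEUDOSRKA (0.0557, 0, 0.0437 and 29.2 CPM; adjusted p = 0.0462) also rose in DIF-OX2 alone. PGL5, a cytosolic enzyme of the oxidative pentose phosphate pathway, was at 28.0, 26.4, 32.6 and 2.54 CPM (adjusted p = 0.00245), and FBA5 at 241, 263, 295 and 12.6 CPM (adjusted p = 0.00786). AT1G13650 (adjusted p = 0.00939) and AT5G35777 (adjusted p = 0.0146) were likewise lower in induced DIF-OX2. In all the Dex effect differed for 1309 genes by edgeR, 792 more positive and 517 more negative in DIF-OX2. None of the 10 largest fitted rises is described as an F-box gene in the reference. The count was 1993 by DESeq2 and 3681 with only these 8 libraries in the fit, of which 1764 were more positive and 1917 more negative. Without replicate 1 of DIF-OX2 on Dex it was 1200, with 589 and 611, so the more frequent direction turned in both settings. It was 257 and 313 without replicate 1 and 2 of Col-0, 190 and 251 without those of Col-0 on Dex, 256 and 272 without those of DIF-OX2, and 239 without replicate 2 of DIF-OX2 on Dex. Of the 8 genes named, 5 lost the call without at least 1 library: PSEUDOSRKA without any of the 8 (adjusted p = 0.0687 to 1), AT1G47980 without replicate 1 or 2 of Col-0, replicate 1 of Col-0 on Dex or replicate 2 of DIF-OX2 on Dex (0.104, 0.0931, 0.0516, 0.0550), CYS2 without the same Col-0 libraries (0.0553, 0.0689, 0.0534) and AT3G10590 without replicate 2 of Col-0 (0.128). AT5G35777 lost it without replicate 1 of Col-0 (0.0517), replicate 1 or 2 of Col-0 on Dex (0.0546, 0.0633), replicate 2 of DIF-OX2 (0.0575) or replicate 2 of DIF-OX2 on Dex (0.108).

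Without Dex, DIF-OX2 differed from Col-0 in 2 genes by edgeR, both lower in the line, with 262 genes at an unadjusted p under 0.05. CYP78A5 had no count in DIF-OX2 and 10.5 ± 0.689 CPM in Col-0, at least 84.4-fold lower (adjusted p = 0.00393). CYP82C4 stood at 23.8 ± 4.09 CPM in DIF-OX2 and 119 ± 13.6 in Col-0 (log2 fold change −2.32, adjusted p = 0.0212). On Dex its levels lay closer, at 46.1 ± 9.04 and 55.5 ± 8.13 CPM, and edgeR did not call it (−0.26, adjusted p = 0.361). Without Dex, DESeq2 called 6 genes and limma-voom 2. With only these 4 libraries in the fit 0 genes passed (adjusted p = 0.227 for each gene). The call of CYP78A5 ended without replicate 2 of Col-0 (adjusted p = 0.0531). That of CYP82C4 ended without any 1 of the 4 libraries (0.112 to 0.510). Camera called 7 lists, all lower in the line, and 0 with an estimated correlation, for which the lowest adjusted p was 0.213; fry called 0.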

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

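Except for the last sentence, the results in this part come from the planned test of the difference between both Dex effects, and no test here was chosen after the result was seen. The effect of Dex differed between DIF-OX2 and Col-0 for 1309 genes by edgeR. More positive in DIF-OX2 were AT1G47980 (adjusted p = 0.0184), PSEUDOSRKA (adjusted p = 0.0462), CYS2 (adjusted p = 0.0102) and AT3G10590 (adjusted p = 0.0109). More negative were AT5G35777 (adjusted p = 0.0146), FBA5 (adjusted p = 0.00786), AT1G13650 (adjusted p = 0.00939) and PGL5 (adjusted p = 0.00245). These genes drew attention because the difference itself passed the test. In Col-0 Dex changed 0 genes by edgeR, with 566 at an unadjusted p under 0.05, and 0 by DESeq2 and limma-voom.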

How the results depend on the processing

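The fit without both dal-2 libraries is the only test here chosen after the result was seen. Genes changed between DIF-OX2 and Col-0 on Dex numbered 4549, and 6892 with only the libraries of the comparison, 7065 without both dal-2 libraries and 2461 at a 2-fold minimum. The dal-2 comparison gave 7011 genes, 2258 with only its own libraries and 3976 at a 2-fold minimum. Dex in DIF-OX2 gave 5023 genes, 7632 without both dal-2 libraries and 2698 at a 2-fold minimum. The difference of both Dex effects gave 1309 genes, 1993 by DESeq2 and 3681 without dal-2, which is the same fit as with only its own libraries. DIF-OX2 without Dex gave 2 genes, 6 by DESeq2 and 0 with only its own libraries. The 2-fold counts are lower because the requirement is stricter. For the other settings the cause was not tested, but fits without dal-2 no longer share its wider replicate spread. Dex in Col-0 gave 0 genes in every setting run, with 566 at an unadjusted p under 0.05 by edgeR.

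With 1 library left out, which leaves fewer samples, the counts ranged from 1343 to 3303 for DIF-OX2 on Dex, 3891 to 8352 for dal-2, 1394 to 3645 for Dex in DIF-OX2, 190 to 1200 for the difference of both Dex effects and 0 to 1 for DIF-OX2 without Dex. Genes higher in both main comparisons ranged from 458 to 1470 and genes lower in both from 365 to 2335. With an estimated correlation 0 lists were called in DIF-OX2 on Dex and 0 in dal-2, against 14 and 12 with the preset one.

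The replicate numbers were used as a replicate block although nothing in the labels says that they pair the samples. Of 10 pairs of groups, 8 had replicate deviations correlated above 0 and 4 above 0.1. The 3 pairs among Col-0, Col-0 on Dex and DIF-OX2 without Dex were correlated at 0.281, 0.298 and 0.458, so a pairing of these groups is not excluded. With the block the counts were 5008 for DIF-OX2 on Dex, 7479 for dal-2, 5470 for Dex in DIF-OX2, 1525 for the difference of both Dex effects and 1 for DIF-OX2 without Dex, and 15 and 12 lists were called in the main comparisons. The 12 in dal-2 were 3 higher and 9 lower, against 2 and 10 without the block, and the root markers were not among them (adjusted p = 0.0508). Among results of named genes 186 were unchanged with the block, 6 lost the call and 2 gained one. The calls lost were those of CYP82C4 in DIF-OX2 without Dex, which leaves CYP78A5, of PSAN and GAPA2 in DIF-OX2 on Dex, of ELF4 and AT1G26410 in dal-2 and of PSEUDOSRKA for the difference of both Dex effects; HSP101 and TMM gained one in DIF-OX2 on Dex.

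Without 1 library the log2 fold change turned for some genes. It ranged from −0.0395 to 0.187 for DAL (MORF2) with Dex in Col-0. In DIF-OX2 on Dex the range was −0.85 to 1.00 for matK, −0.22 to 1.52 for ASN1, −0.27 to 1.33 for FT and −4.03 to 3.45 for CRU1. In dal-2 it was −0.52 to 0.63 for HSP101, −2.30 to 2.93 for ASN1, −0.58 to 1.3 for FT and −1.44 to 6.85 for ELF4. Of these only ELF4 was called with all libraries. Over all named genes and libraries left out, 609 results kept call and direction, 189 lost the call, 3 gained one and 11 turned. By DESeq2 186 results of named genes were unchanged in call and direction, 5 lost the call and 3 gained one, and with only the libraries of the comparison 147 were unchanged, 34 lost the call and 7 gained one.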

Other observations

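The tests in this part were chosen after the result was seen, except those of depth and of a deletion that spans neighbouring genes. Iron deficiency genes went opposite ways in the 2 main comparisons. Of 18 tested, 9 rose and none fell in DIF-OX2 on Dex (median log2 fold change 1.44, camera adjusted p = 0.00287, adjusted p = 0.424 with an estimated correlation), and 12 fell and none rose in dal-2 (median −2.89). The list was drawn up after the falls of IRT1 and CYP82C4 in dal-2 had been seen, so its test there is not given; of the 16 other members 10 fell and none rose in dal-2 (median −2.73). The regulator bHLH38 had a log2 fold change of 2.95 (adjusted p = 0.00848) in DIF-OX2 and −5.83 (adjusted p = 0.00246) in dal-2. The root reductase FRO2 fell in dal-2 (−6.98, adjusted p = 1.39e-04) and was not called in DIF-OX2 (adjusted p = 0.986), while FRO3 rose in DIF-OX2 (1.51, adjusted p = 0.00200). Camera with the preset correlation also called this list lower for Dex in Col-0 (adjusted p = 2.61e-15), where 0 of its genes were called by edgeR, so its call alone carries little weight. Of 14 root markers 3 rose and none fell in DIF-OX2 on Dex, where the list was not called (median 0.37, camera adjusted p = 0.328, adjusted p = 0.758 with an estimated correlation) and 7 fell and 1 rose in dal-2 (median −0.68, camera adjusted p = 0.0424, adjusted p = 0.648 with an estimated correlation). A lower share of root in dal-2 as the only change would lower root genes alike. PYK10 rose there (log2 fold change 1.3, adjusted p = 0.00231) while IRT1 fell (−9.40, adjusted p = 9.03e-05). These genes cannot exclude a lower share of root beside other changes, which stays open. In DIF-OX2 on Dex IRT1 was not called (−0.04, adjusted p = 0.949).

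Of 49 WRKY transcription factors 22 rose and none fell in DIF-OX2 on Dex (median 1.07, camera adjusted p = 7.46e-12, adjusted p = 0.126 with an estimated correlation), and 18 rose and 1 fell in dal-2 (camera adjusted p = 2.24e-05, adjusted p = 0.25 with an estimated correlation). Pentatricopeptide repeat genes, many of which serve organellar RNA, rose in dal-2 in 65 of 241 cases and fell in 19 (camera adjusted p = 9.04e-05, adjusted p = 0.520 with an estimated correlation), against 2 and 24 in DIF-OX2 on Dex (camera adjusted p = 0.0878). Auxin-responsive SAUR genes fell in 19 of 53 cases in DIF-OX2 and 26 in dal-2 and rose in 5 cases in each (camera adjusted p = 8.33e-04 and 1.94e-04, with adjusted p = 0.329 and 0.275 with an estimated correlation). Of 46 histone genes 28 fell and 3 rose in dal-2 (camera adjusted p = 2.24e-05, adjusted p = 0.25 with an estimated correlation).

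CYP78A5 had 469 counts over the Col-0 libraries and 0 in the 4 DIF-OX2 libraries. An action of the induced product on the gene is argued against by the libraries without Dex, where 0 counts allow at most 0.0118 of the Col-0 level. Another accession, or many variants that silence genes, would leave more genes at 0. Only 1 gene was at 0 in all DIF-OX2 libraries with at least 40 Col-0 counts. Variants that do not bring genes to 0 are not covered by this count. A deletion spanning the nearest tested genes is argued against by their levels, the lower of which, that of PGL1, was 0.849 of the Col-0 level. A deletion that ends before these genes is not covered. An insertion or small deletion inside the gene may explain the 0 counts and stays open, since reads are needed to see it.

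The dal-2 replicates differed more than those of other groups, and a different hour of harvest is a candidate explanation: the clock list had a median absolute log2 difference of 3.53 between them, against 0.258 to 0.364 in the other groups, and all 10 morning and evening genes moved as such a shift needs. Depth does not account for it, since with all libraries thinned to 1 total the spread in dal-2 was 1.7 times the largest of the other groups. A small share of Col-0 plants mixed into replicate 2 could raise genes there but hardly lower any 4-fold. If this were the only difference, under 5% of the genes over 4-fold apart would be higher in replicate 1. Replicate 1 had the lower light harvesting level, and 35.6% (187 of 525) were higher in it. That argues against mixing alone, but not against mixing beside a shift of hour. The age of 20 against 21 days cannot be told apart from the replicate, with 1 library of each age. No other biological explanation was tested.

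By camera with the preset correlation the anthocyanin list was higher in DIF-OX2 on Dex (adjusted p = 0.0260) and lower in dal-2. With an estimated correlation camera called it in neither (adjusted p = 0.590 and 0.217). The part of scaling stays open: the DIF-OX2 median was at least 0.788 under 2 other scalings, but these moved the median of all genes there by at most 0.0026 and could not have turned it. One library does not decide the direction: the DIF-OX2 median without each library in turn was at least 0.657 and the dal-2 median at most −2.81. A different hour of harvest of 1 dal-2 library would set its replicates apart, but the median absolute difference of the list was 0.712 against a dal-2 median of −3.70. An hour that differs between both dal-2 libraries and Col-0 could move both alike, so it is not covered by this test and stays open. The age of the dal-2 plants could account for the fall and stays open, since 0 Col-0 libraries were older than 12 days.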
